A study of Arabidopsis thaliana with 32 samples.

How the data were processed

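Roots of 5-week-old Arabidopsis thaliana plants grown in hydroponics were sampled 6 h after 20 µM zaxinone in 1% acetone, or 1% acetone alone (mock), had been added to the medium. Zaxinone is a small apocarotenoid, a cleavage product of carotenoids. There were 4 genotypes, the wild type Col-0 and the mutants d14, kai2 and max2, each with 4 zaxinone and 4 mock libraries, so that 32 libraries formed 8 groups. D14 is the α/β-hydrolase receptor of strigolactones, KAI2 its paralog that takes part in karrikin responses, and MAX2 the F-box protein that acts with both. Groups and replicate numbers were taken from the sample titles. The labels call the 4 libraries of a group replicates and do not say whether they came from separate cultures, so p-values measure the spread between these libraries.

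Polyadenylated RNA was sequenced in paired-end mode, per the labels' protocols, which leave open whether the libraries kept the strand. HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build, the annotation and the tool that counted reads are not given in the sources used here. Each genotype had its own table of zaxinone against mock. Per the file headers, the deposited tables give for each gene the raw read counts of the 8 libraries, normalized counts (a signal on the scale of counts), FPKM values, a log2 fold change, a p-value and an adjusted p-value. The authors' normalized count was the raw count divided by 1 factor per library, from 0.788 to 1.29. In Col-0 zaxinone replicate 2 the deposited normalized column held 1 constant, so its factor was recovered from the authors' group mean. The model behind the authors' log2 fold changes and p-values is not stated.

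The deposited tables list selected genes: each listed gene had an adjusted p-value under 0.05 and an absolute log2 fold change of at least 1. The ranks of the deposited p-values implied 25041, 24718, 24625 and 24534 tested genes in Col-0, d14, kai2 and max2, and unlisted genes were not analysed here. A test over all genes was therefore not possible, and the authors' deposited calls, counted by direction, were taken as the result of each zaxinone comparison. This course had been set in advance for tables of that kind, in place of the planned count test. All comparisons, gene lists, the rule for named genes and most other settings were fixed before the data were examined.

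Each library's total depth was recovered from its counts and FPKM values and came to between 42.8 and 101.9 M fragments. The listed genes held 2.94 to 8.48 M counts per library, which was 4.63 to 13.3% of the total. The authors' factors and these totals differed in their zaxinone-to-mock balance by less than 0.01 on the log2 scale in each genotype. Replicate libraries differed from each other by far more than sampling noise, with chi-square values per degree of freedom from 16.8 to 287, so all were kept as separate replicates. A group in which all 4 libraries had 0 counts was given a floor of 3 counts per library, and folds against it are lower bounds that cover counting error only.

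Listed genes were described with edgeR 4.0.16 (quasi-likelihood test on the deposited counts, with the authors' factors as library scale) in R 4.3.3. Benjamini-Hochberg adjustment ran over the number of tests implied, with unlisted genes entered as unchanged. The largest deposited p-values implied ranks of about 5893, 6669, 6429 and 5239 in Col-0, d14, kai2 and max2. Far more genes than those listed had thus passed the authors' adjusted p of 0.05. The edgeR adjusted p-values of these comparisons therefore tend to be too high, and one just over 0.05 does not show that a gene did not change. Because the listed genes had been selected on the same libraries, the edgeR fit gives sizes and spreads and is no independent test. Its fold changes correlated with the authors' across listed genes with r = 0.999 in each genotype. Differences of the zaxinone effect between a mutant and Col-0 were tested as the genotype by treatment term in edgeR on the 16 libraries, over genes listed in both tables. Mutant and Col-0 mock libraries were compared over the same genes, scaled by library totals. Lists were compared between genotypes with fry of limma 3.58.1. Other settings used DESeq2 1.42.0, limma-voom, TMM, another filter on low counts, stricter thresholds, the replicate number as a block, all libraries in 1 fit and each library left out. TMM over listed genes assumes that most of them did not change, which the selection rules out. Its values show only how calls move with the scaling, and they set no bound on the error of scaling.

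Overlaps between tables were tested with Fisher's exact test against the 38095 genes of the reference annotation as an approximate background. The 33 gene lists, written from textbook knowledge, were tested with a 2-sided Fisher's exact test against the 27562 protein-coding genes of that annotation, with Benjamini-Hochberg adjustment over 66 tests per genotype. The stricter background was the 3443 genes listed in any table. A camera test with a preset or an estimated correlation was not run, since it needs unselected genes. Fisher's exact test treats genes as independent, so genes that change together or share reads can make its p-values too small. The models of the zaxinone comparisons and of the differences between genotypes, but not those of the mock comparisons, were tested on simulated counts in which 200 genes had been changed by a known amount. For the zaxinone comparisons the fit recovered 61 to 69% of changes of 1 on the log2 scale and 93 to 96% of changes of 2. These simulated calls were adjusted over the listed genes alone, a milder adjustment than in the real fit. Of them 2.48 to 6.78% were false. For the differences between genotypes the fit recovered 41 to 45% of changes of 1 and 81 to 92% of changes of 2. There 200 of 1049 to 1290 genes had been changed, and with fewer true differences a smaller share would be recovered.

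Named genes followed a fixed rule. It took the 3 targeted genes, the 8 largest rises and 8 largest falls per genotype at a mean of at least 50 normalized counts without overlap of the groups, and up to 4 members per list with the smallest adjusted p. It also took the 5 largest differences from Col-0 per direction and mutant, and the 5 largest mean changes per direction among genes listed in 3 or 4 genotypes. This gave 194 genes in 411 gene and genotype pairs. Genes without a symbol are named by their locus code. Values of near-identical neighbours, among them AT4G19750, AT4G19760, AT4G19770 and AT4G19800, UGT73B2 and UGT73B3, the GSTU genes, and AT4G10265 and WIP4, are uncertain because shared reads could be split between them. The same holds for AT5G50550, which has a near-identical copy, and for genes with an antisense neighbour. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.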

Results

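RNA from roots of 4 Arabidopsis thaliana genotypes was compared between zaxinone and mock treatment after 6 h, with 4 libraries per group. The series title names the hydrolase receptor D14 as its subject, and the design sets the wild type Col-0 beside the mutants d14, kai2 and max2, named after D14, its paralog KAI2 and the F-box protein MAX2. Library depth ranged from 67.6 to 101.9 M fragments (M, mega) in Col-0, 46.9 to 73.9 M in d14, 42.8 to 68.8 M in kai2 and 47.9 to 64.1 M in max2. Levels are given below as normalized counts (mean ± SD, n = 4 libraries per group) and changes as log2 fold changes of zaxinone over mock (± SE, edgeR), unless the authors' deposited table is named. Normalized counts were scaled within each genotype, so levels cannot be compared between genotypes. Genes called higher or lower are those of the authors' deposited tables, in which only genes past an adjusted p of 0.05 and an absolute log2 fold change of 1 are listed.

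The targeted genes came first. KAI2 was listed in kai2 alone among the 4 tables, where its counts rose from 163 ± 19.6 to 523 ± 66.1 with zaxinone, a change of 1.68 ± 0.18 on the log2 scale. D14 and MAX2 were listed in no table, so their levels were not analysed here and the genotype labels could not be checked against them. A lesion that leaves transcript in place would not show in these counts either.

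In Col-0 roots zaxinone raised genes of xenobiotic detoxification, abscisic acid response and suberin formation, and lowered genes of the low oxygen response. Of 38 detoxification genes, 28 rose and none fell (Fisher's exact test, adjusted p = 1.2e-32). UGT73B2, a UDP-glucosyltransferase, rose from 310.4 ± 29.0 to 10189 ± 1383 normalized counts, and the oxophytodienoate reductase gene OPR1 rose from 1237 ± 139 to 20539 ± 1552. The glutathione transferase genes GSTU22 and GSTU7 rose by 3.64 ± 0.17 and 3.54 ± 0.17 on the log2 scale. In the same list the cytochrome P450 gene CYP81D11 rose from 162 ± 50.2 to 5396 ± 485 and the ABC transporter gene ABCG40 rose from 7.92 ± 4.66 to 768 ± 539. Outside it the oxidoreductase gene AT1G60750 rose from 22.7 ± 10.7 to 3309.8 ± 871.

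Abscisic acid genes moved in 1 direction in Col-0. Of 22 response genes 14 rose and none fell (adjusted p = 6.7e-15), and of 12 metabolism genes 4 rose and none fell (adjusted p = 0.00366). NCED3, which encodes a rate-limiting enzyme of abscisic acid synthesis, rose from 93.5 ± 35.1 to 1421 ± 151, while CYP707A1 and CYP707A2, whose products break the hormone down, rose by 1.27 ± 0.18 and 2.79 ± 0.37 on the log2 scale. The phosphatase gene HAI1 rose from 83.8 ± 22.3 to 1909 ± 445, the dehydrin gene LTI30 from 5084 ± 424 to 25957 ± 1456 and the transcription factor gene RD26 from 847 ± 49.6 to 3224 ± 326. The late embryogenesis abundant gene AT5G66780 rose from 5.77 ± 2.33 to 628 ± 217, and AT3G17520, of the same class, had 0 counts in all 4 mock libraries and was at least 21.7-fold higher with zaxinone. With the stricter background of listed genes the metabolism list no longer passed (adjusted p = 0.0548).

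Of 17 endodermis and suberin genes 6 rose and none fell in Col-0 (adjusted p = 1.4e-04). CASP5, a protein of the Casparian strip, rose from 36.1 ± 13.4 to 227 ± 38.4, and the suberin genes KCS2, CYP86B1 and ASFT rose by 1.84 ± 0.23, 1.72 ± 0.25 and 1.42 ± 0.24 on the log2 scale. Of 14 heat shock genes 5 rose (adjusted p = 6.2e-04), among them DREB2A from 850.3 ± 123 to 4547 ± 460.1 and HSFA2 from 27.9 ± 13.1 to 93.4 ± 14.9. Of 9 early touch and stress genes 4 rose (adjusted p = 0.00117), among them the zinc finger gene ZAT12 from 934 ± 206 to 5973 ± 1032. With the stricter background the suberin, heat shock and touch lists did not pass (adjusted p = 0.0548, 0.751 and 0.0548).

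Low oxygen genes fell in Col-0: 11 of 13 were lower and none was higher (adjusted p = 2.7e-14). HRE1, an ethylene response factor induced under hypoxia, fell from 23635 ± 1922 to 3188 ± 470.1, the plant cysteine oxidase genes PCO1 and PCO2 fell from 7214 ± 1503 to 1829 ± 581 and from 6625 ± 1867 to 1215 ± 360.3, and the hemoglobin gene HB1 fell from 20564 ± 6279 to 4164 ± 1013. The ethylene-forming enzyme gene ACO1 fell from 9559 ± 3927 to 1627 ± 443. Of 19 glucosinolate genes 4 fell and 2 rose (adjusted p = 0.0179 for the falls), with the regulator gene MYB28 at -1.65 ± 0.23 and MAM1 at -1.09 ± 0.21 on the log2 scale. Of 22 salicylic acid and immune genes 4 fell and 3 rose (adjusted p = 0.0279 for the falls), SARD1 falling from 1885 ± 485 to 569 ± 135 and the camalexin gene PAD3 rising from 458 ± 103 to 1468 ± 306. Both of these lists lost their call with the stricter background (adjusted p = 0.923 in each).

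Among the largest falls in Col-0 were kinase, cytochrome P450 and chitinase-family genes. AT1G51810, a leucine-rich repeat kinase gene, fell from 143 ± 43.9 to 0 counts in all 4 zaxinone libraries, at least 47.8-fold lower. The cytochrome P450 gene CYP710A3 fell from 1524 ± 376 to 23.4 ± 17.8, the transmembrane protein gene AT1G44010 from 314 ± 87.0 to 2.68 ± 3.00 and the extensin-like gene AT4G08380 from 2173 ± 865 to 50.2 ± 20.3. The tandem chitinase-family genes AT4G19750, AT4G19760 and AT4G19770 changed by -6.19 ± 0.57, -6.82 ± 0.55 and -5.78 ± 0.51 on the log2 scale, with shared reads possible between them.

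Counted over the authors' deposited table, 1835 genes changed in Col-0, 937 higher and 898 lower, with a median absolute log2 fold change of 1.58. In 1685 of them the 4 zaxinone libraries all lay on one side of the 4 mock libraries, which the selection of listed genes on these same libraries favours. At an absolute log2 fold change of at least 2 the count was 560.

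The d14 mutant, named after the strigolactone receptor, is the genotype that the series title asks about. Its roots showed rises in detoxification, abscisic acid response, suberin and heat shock genes and falls in low oxygen and nitrate genes. Of 38 detoxification genes 33 rose and none fell (adjusted p = 1.2e-36), UGT73B2 rising from 101 ± 11.3 to 6869 ± 1126, GSTU24 from 291 ± 37.5 to 5884 ± 401 and GSTU7 from 705 ± 58.5 to 8165 ± 563. Of 22 abscisic acid response genes 16 rose and none fell (adjusted p = 2.0e-15). RD29A rose from 163 ± 29.1 to 2679 ± 825, ABF3 from 1222 ± 75.1 to 7579.8 ± 1601 and RD26 from 438 ± 61.4 to 3059.9 ± 869. NCED3 rose from 54.0 ± 19.7 to 762 ± 98.7, but the 3 of 12 abscisic acid metabolism genes that rose did not make that list pass (adjusted p = 0.095).

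Suberin and stress genes rose in d14 as well. Of 17 endodermis and suberin genes 8 rose and none fell (adjusted p = 7.2e-06), KCS2 rising from 394 ± 25.3 to 2895 ± 806, CYP86B1 from 624 ± 36.5 to 3267 ± 723 and GPAT5 from 654 ± 64.3 to 2919 ± 559. Of 14 heat shock genes 9 rose (adjusted p = 4.3e-08), among them HSP70-4 from 444 ± 56.7 to 1954 ± 416 and DREB2A from 407 ± 48.6 to 2922 ± 991. Of 9 touch and stress genes 4 rose (adjusted p = 0.00442, and 0.198 with the stricter background), with ZAT12 from 802 ± 67.5 to 8986 ± 3061 and CBF3 from 0.71 ± 0.492 to 26.0 ± 7.08. In d14 zaxinone replicate 1 several stress and energy genes lay apart from the other 3 libraries, HSP17.4 at 441 against 136 to 184 and the β-glucosidase gene BGLU30 at 24091 against 1965 to 4724.

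In d14, 10 of 13 low oxygen genes fell and none rose (adjusted p = 2.0e-12), HRE1 falling from 18976 ± 3376 to 2398 ± 526 and SUS4 from 16930.4 ± 7902 to 3307 ± 412. Of 19 glucosinolate genes 6 fell and 2 rose (adjusted p = 1.2e-04, and 0.0722 with the stricter background), MAM1 falling from 16899.9 ± 3459 to 3787 ± 200.4 and MYB28 from 2309 ± 222 to 699 ± 73.2, while the β-glucosidase gene BGLU23 rose from 43191 ± 1939 to 271847 ± 95082. Of 17 nitrate genes 5 fell and the ammonium transporter gene AMT1;1 rose (adjusted p = 8.3e-04 for the falls), though with TMM over the listed genes AMT1;1 had an adjusted p of 0.152. The nitrite reductase gene NIR1 fell from 34455 ± 2128 to 14805 ± 1315, and G6PD3 and UPM1 changed by -1.91 ± 0.14 and -1.15 ± 0.12 on the log2 scale. Of 14 cytokinin genes 5 rose and 3 fell (adjusted p = 0.00325 and 0.0368), the response regulators ARR4, ARR5 and ARR6 and the oxidase gene CKX4 among the rises. Of 22 salicylic acid and immune genes 5 rose and 4 fell (adjusted p = 0.0224 and 0.0212). The cytokinin and immune calls were lost with the stricter background, at adjusted p = 1 and 1 for cytokinin and 1 and 0.999 for immune genes.

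Among the largest changes in d14, the malic enzyme gene NADP-ME1 rose from 3.75 ± 2.54 to 248 ± 52.4, YLS9 from 88.4 ± 25.7 to 5292 ± 1865 and the glycine-rich protein gene GRP3S from 41.2 ± 18.1 to 2138 ± 1192. AT4G19750 fell from 2539 ± 422 to 16.7 ± 10.7, AT1G44010 from 537 ± 81.9 to 3.99 ± 2.62 and the resistance-type gene AT5G45230 from 103 ± 23.3 to 2.42 ± 2.77. The authors' deposited table listed 2336 genes in d14, 1468 higher and 868 lower. The edgeR fit called 1317 higher and 783 lower, and with TMM scaling over the listed genes, which moved their median by -0.91 on the log2 scale, 566 higher and 868 lower, so that the share of rises went from 62.7 to 39.5%. At an absolute log2 fold change of at least 2 the count was 847.

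In kai2, named after the karrikin-pathway paralog of D14, zaxinone raised detoxification, abscisic acid, suberin and sulfur genes. Of 38 detoxification genes 26 rose and none fell (adjusted p = 1.3e-27), UGT73B2 rising from 179 ± 73.4 to 7349.6 ± 354, OPR1 from 711 ± 87.3 to 10389.5 ± 479.7 and GSTU19 from 8176 ± 1107 to 70188 ± 9461. Of 22 abscisic acid response genes 15 rose and none fell (adjusted p = 6.0e-16), ABI2 rising from 282 ± 38.3 to 1615 ± 369 and HB7 from 1173 ± 89.9 to 5315 ± 1313. In kai2 zaxinone replicate 1 ABI2 stood at 2167 against 1392 to 1459 in the other 3 zaxinone libraries and HB7 at 7281 against 4568 to 4741, and RD26 and LEA7 were higher there as well. Of 12 abscisic acid metabolism genes 4 rose (adjusted p = 0.00561, and 0.0861 with the stricter background), NCED3 from 67.2 ± 36.9 to 1426 ± 146. The edgeR calls of CYP707A2 and NCED2 in kai2 were lost in 5 and 8 other settings. Of 17 endodermis and suberin genes 7 rose (adjusted p = 2.0e-05), KCS2 from 379 ± 127 to 1819 ± 327 and CASP5 from 38.4 ± 15.7 to 147 ± 35.2.

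Of 13 sulfur limitation genes 6 rose and 1 fell in kai2 (adjusted p = 4.2e-05 for the rises). The sulfate assimilation genes APR3 and APR2 rose from 1473 ± 332 to 5924 ± 1044 and from 1108 ± 159 to 2723 ± 452, LSU2 rose from 100.02 ± 39.3 to 349 ± 93.4, and the sulfate transporter gene SULTR1;1 fell from 5095 ± 225 to 1709.8 ± 295. Of 24 iron deficiency genes 6 rose and 3 fell (adjusted p = 0.0019 for the rises, and 0.491 with the stricter background). The transporter gene ABCG37 rose from 13831 ± 1357 to 33364 ± 1946, and the regulator genes FIT and BHLH39 rose by 1.13 ± 0.15 and 1.45 ± 0.24 on the log2 scale. Of 14 cytokinin genes 4 rose and IPT5 fell, of 22 immune genes 4 rose and 2 fell, and of 12 clock genes 3 were listed lower and ELF4 higher (adjusted p = 0.00938, 0.0439 and 0.0256). None of these 3 calls held with the stricter background (adjusted p = 1, 1 and 0.312). PRR9, a clock gene, fell from 669 ± 87.4 to 121 ± 52.6.

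For low oxygen genes in kai2 1 mock library stood apart. The authors' deposited table listed 4 of 13 as lower and none as higher (adjusted p = 0.00329, and 1 with the stricter background). HRE1 fell from 9745 ± 1354 to 1464 ± 320.0 and HB1 from 19128 ± 21668 to 2162 ± 446. In kai2 mock replicate 1 HB1 stood at 51508 against 6829 to 10974 in the other mock libraries, PCO2 at 6199.7 against 695 to 1418, and the shoot gene LHCB1.2 at 94.3 against 2.45 to 11.9. PCO2 reached an adjusted p of 0.0518 with edgeR. PCO1 had an adjusted p of 0.0477 in the full data and of 0.0870 without kai2 mock replicate 1, within a range of 0.00181 to 0.148 over all other settings.

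The largest rises in kai2 included ABCG40 from 7.50 ± 1.37 to 551 ± 160.0, the heat shock factor gene HSFA6B from 7.93 ± 6.57 to 385 ± 165 and the thalianol synthase gene THAS1 from 74.1 ± 39.8 to 3348 ± 1188. AT1G44010 fell from 227 ± 54.0 to 0.54 ± 0.637, LURP1 from 114 ± 29.1 to 1.201 ± 1.39 and AT4G08380 from 2928 ± 765 to 73.3 ± 27.2. In total the authors' deposited table listed 1833 genes in kai2, 1025 higher and 808 lower. The edgeR fit called 905 higher and 672 lower, and with TMM over the listed genes 580 higher and 799 lower, a share of rises of 42.1% in place of 57.4%, after a shift of the median by -0.52. At an absolute log2 fold change of at least 2 the count was 571.

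In max2 the rises again lay in detoxification, abscisic acid and suberin genes. Of 38 detoxification genes 30 rose and none fell (adjusted p = 3.3e-37), CYP81D11 rising from 26.9 ± 10.4 to 2250.1 ± 659.9 and UGT73B2 from 94.6 ± 19.3 to 5065 ± 886. Of 22 abscisic acid response genes 12 rose and none fell, and of 12 metabolism genes 4 rose (adjusted p = 8.1e-12 and 0.00363). ABF3 rose from 819.9 ± 138 to 5274 ± 981, HAI1 from 80.2 ± 12.5 to 708 ± 341 and NCED3 from 168 ± 28.1 to 679.8 ± 177. The edgeR call of CYP707A2 in max2 was lost in 7 other settings, with an adjusted p of 0.122 with the replicate number as a block. Of 17 endodermis and suberin genes 6 rose (adjusted p = 1.5e-04), CYP86B1 from 586 ± 23.7 to 1915 ± 236 and ASFT from 2861 ± 468 to 7399 ± 989. Of 9 touch and stress genes 4 were listed higher (adjusted p = 0.00119), ZAT12 rising from 957 ± 77.4 to 5291 ± 974 and CBF2 from 8.79 ± 4.94 to 60.8 ± 21.8.

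Low oxygen genes were listed in both directions in max2. HRE1 fell from 12427 ± 515 to 3285 ± 779, but 3 of the 13 were listed as higher (adjusted p = 0.037, and 1 with the stricter background), HRE2 rising from 19.5 ± 8.19 to 336 ± 249 (adjusted p = 0.00209 with edgeR and 0.106 with limma-voom). The sucrose synthase gene SUS1 went from 23461 ± 6374 to 48613 ± 16207 (edgeR, adjusted p = 0.044), a call lost without max2 zaxinone replicates 1, 3 and 4 (adjusted p = 0.164, 0.120 and 0.1497), without max2 mock replicates 2 and 3 (0.147 and 0.155), with limma-voom (0.0630) and with TMM over the listed genes (1). WIP4 went from 237 ± 91.0 to 811 ± 533 (edgeR, adjusted p = 0.0592). Of 14 heat shock genes 5 were listed higher (adjusted p = 6.4e-04, and 0.709 with the stricter background), DREB2A rising from 518 ± 32.5 to 2255 ± 546. Of 21 phosphate starvation genes 4 were listed higher (adjusted p = 0.0236), PHT1;4 rising from 367 ± 80.1 to 797 ± 73.3 (adjusted p = 0.131 with TMM over the listed genes) and the acid phosphatase gene PAP17 from 372 ± 136 to 1245 ± 308. Of 19 glycolysis genes 4 rose and of 24 iron genes 4 rose and 1 fell (adjusted p = 0.0206 and 0.0351), GAPC1 from 29821 ± 4235 to 67283 ± 10289.9 and the iron-responsive regulator gene BHLH101 from 5.32 ± 3.16 to 42.0 ± 20.0. Of 14 cytokinin genes 3 fell, all of them isopentenyltransferase genes of cytokinin synthesis, IPT5 from 6468 ± 316 to 1278 ± 280.4, IPT7 and IPT3 (adjusted p = 0.0236). The glycolysis, iron and cytokinin calls were lost with the stricter background (adjusted p = 0.137, 1 and 1).

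Among the largest falls in max2 were AT4G19760 from 1652 ± 608 to 32.6 ± 13.9, the terpenoid cyclase gene AT3G29110 from 1971 ± 837 to 82.2 ± 18.1 and CYP710A3 from 1559 ± 394 to 49.3 ± 18.5. In sum the authors' deposited table listed 1514 genes in max2, 876 higher and 638 lower. The edgeR fit called 740 higher and 521 lower, and with TMM over the listed genes 484 higher and 615 lower, a share of rises of 44.0% in place of 58.7%, after a shift of the median by -0.48. At an absolute log2 fold change of at least 2 the count was 456.

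Lists of strigolactone and carotenoid genes had few listed members, which leaves changes under the authors' threshold open. Of 18 strigolactone and karrikin signalling genes 1 rose and 1 fell in Col-0, 2 rose in d14 and in kai2, and 1 rose in max2, and the list passed in no genotype (lowest adjusted p = 0.452). HB40, a transcription factor gene induced by strigolactones, rose in all 4: from 43.5 ± 17.9 to 372 ± 86.4 in Col-0, from 19.3 ± 8.99 to 142 ± 31.8 in d14, from 29.0 ± 21.9 to 170.1 ± 70.2 in kai2 and from 17.38 ± 3.98 to 76.3 ± 21.4 in max2. CCD7, an enzyme of strigolactone synthesis, rose from 27.3 ± 7.46 to 103 ± 55.4 in Col-0. In kai2 it was listed as higher too, going from 20.7 ± 24.3 to 65.2 ± 18.4, with mock replicate 1 at 56.9 against 6.12 to 11.9 and an edgeR adjusted p of 0.259. The strigolactone biosynthesis list of 6 genes had no other listed member. Of 19 carotenoid genes BCH1, a β-carotene hydroxylase, rose in all 4 genotypes, from 227 ± 32.3 to 1183 ± 258 in Col-0, and the list passed in none (lowest adjusted p = 0.404).

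The remaining lists had few listed members and passed in no genotype. Over the 4 tables together, jasmonate genes were listed 6 times as higher and 3 times as lower, ethylene genes 3 and 4 times, auxin response genes 3 and 0 times, auxin transport genes 1 and 0 times, and phenylpropanoid genes 8 and 4 times. Sugar transport genes were listed 9 times as higher and 1 time as lower, energy starvation genes 7 and 0 times, mitochondrial stress genes 7 and 0 times, and shoot photosynthesis genes 2 and 4 times. Among them the alternative oxidase genes AOX1A and AOX1D rose by 1.63 ± 0.18 and 4.60 ± 0.48 on the log2 scale in Col-0, and the F-box gene KMD4 rose from 5668 ± 604 to 17367 ± 1845. No marker of root hairs, xylem, phloem, root cap or dividing cells was listed in any table, which leaves changes under the authors' threshold open. Over all lists and genotypes 501 members were past the authors' threshold and 498 with p-values adjusted over the list alone. Unlisted members had no p-value and were entered as unchanged, so the second count could not exceed the first.

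**Figure D1:**
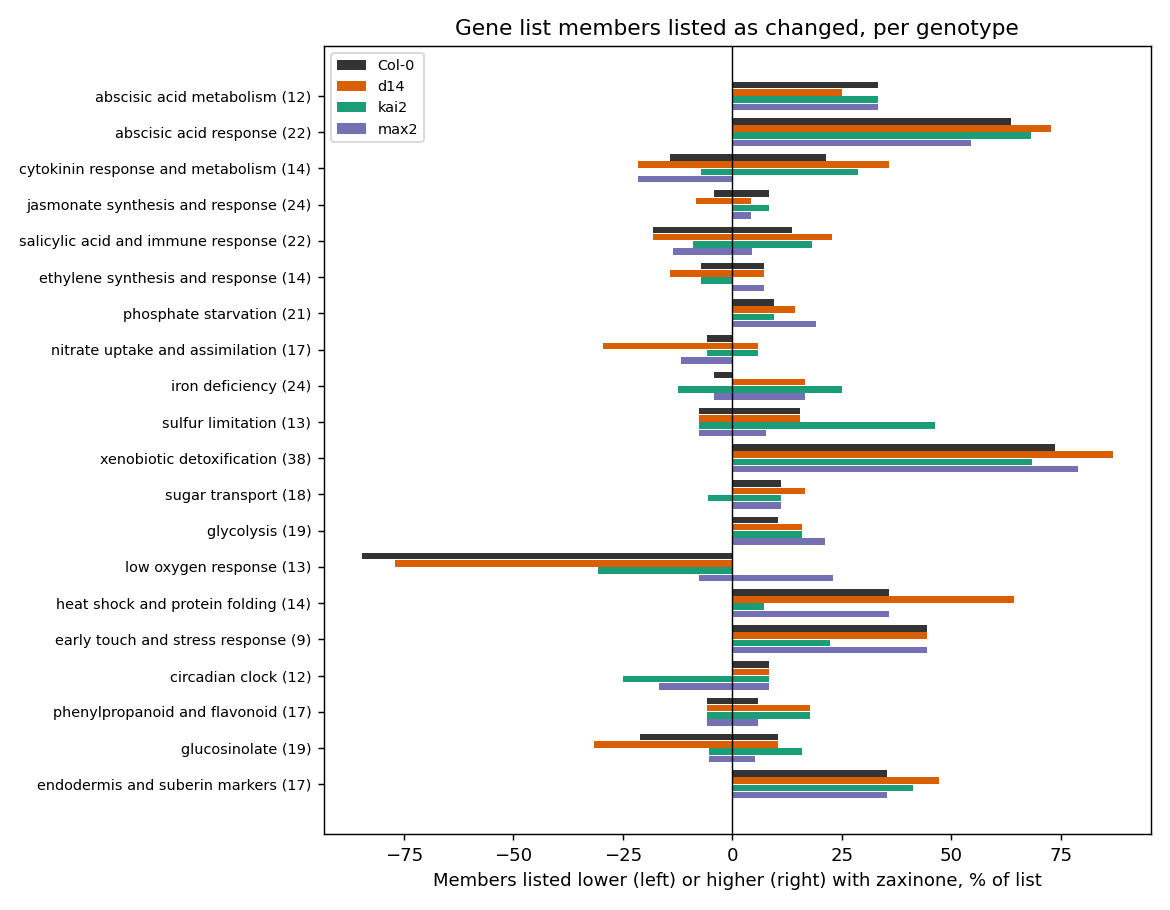
Bars show the percentage of each list's genes (list size in brackets) that the authors' deposited tables give as higher (right of 0) or lower (left of 0) with zaxinone, for the 20 lists with at least 3 listed members in a genotype. Detoxification reached 28, 33, 26 and 30 of 38 genes in Col-0, d14, kai2 and max2, and low oxygen genes fell in 11, 10, 4 and 1 of 13.

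**Figure D2:**
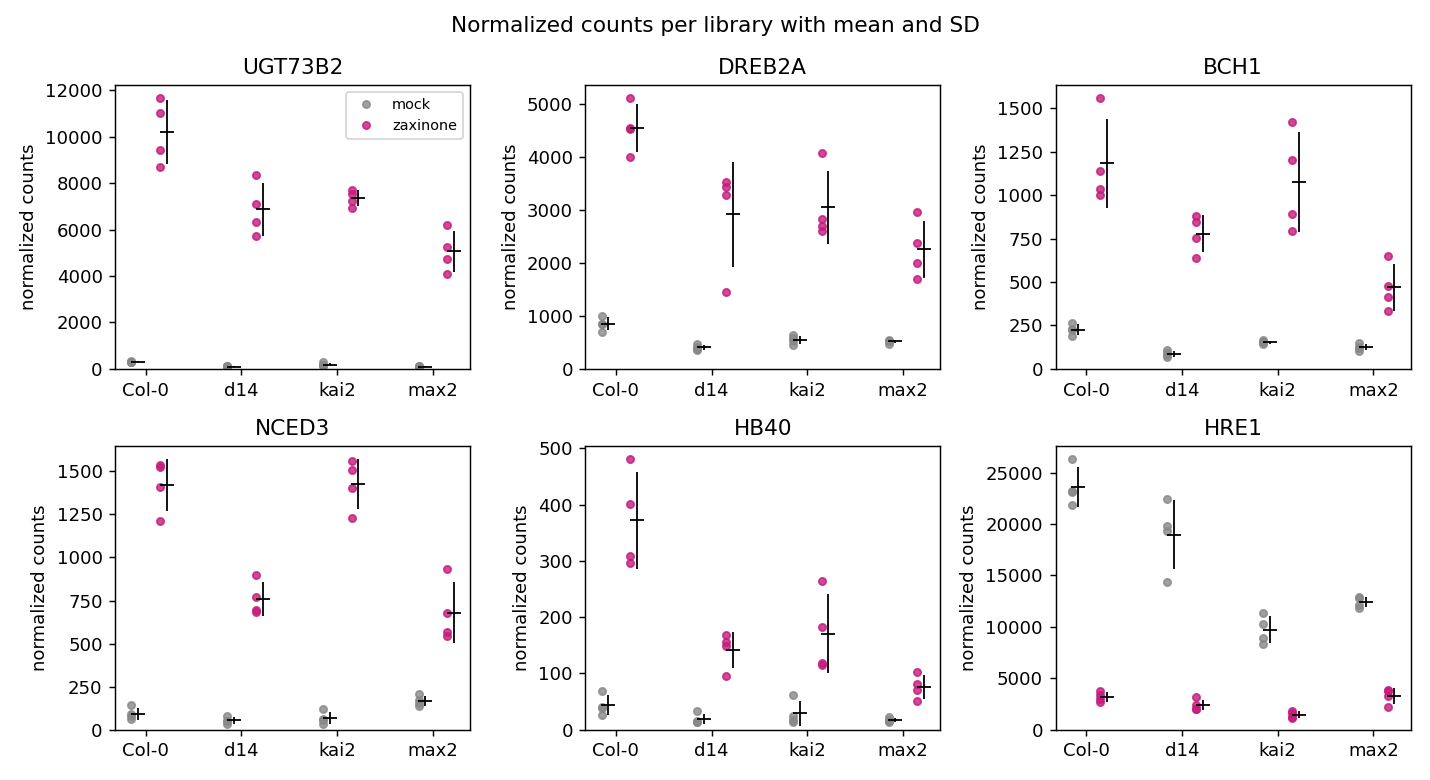
Points are normalized counts of single libraries (grey mock, magenta zaxinone), with the mean and SD of 4 libraries beside them, on linear axes for 6 genes in each genotype. UGT73B2, DREB2A, BCH1, NCED3 and HB40 were higher and HRE1 lower with zaxinone in all 4 genotypes. Counts were scaled within each genotype, so levels cannot be compared between genotypes.

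Which genes responded in more than 1 genotype was asked next. Of 3443 genes listed in any genotype, 827 were listed in all 4, and 826 of these had the same direction in each. Among genes listed in 3 or 4 genotypes the largest mean rises were those of AT3G03341, AT3G17520, ABCG40, AT1G60750 and UGT73B2. The largest mean falls were those of AT1G51810, AT2G37800, AT4G19800, AT3G47170 and the zinc transporter gene ZIP10, each with 0 counts in all 4 zaxinone libraries of at least 2 genotypes. AT2G37800 fell from 54.2 ± 22.5 to 0 in Col-0, at least 18.1-fold lower, and at least 31.8-fold, 28.4-fold and 16.2-fold lower in d14, kai2 and max2.

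Of the 937 genes that rose in Col-0, 713 also rose in d14, 599 in kai2 and 576 in max2, where independent lists would share 36.1, 25.2 and 21.5 genes. Of the 898 that fell, 574, 537 and 463 also fell, against 20.5, 19.0 and 15.04. In each of the 12 pairs of tables and directions Fisher's exact test gave an adjusted p below what can be printed, and the ratio of observed to independent overlap lay between 19.5 and 34.1 with the reference annotation as an approximate background. With the tests implied as background, added after the results were seen, it lay between 12.6 and 22.0. The 545 Col-0 genes not listed in d14 had a median absolute log2 fold change of 1.298 in the authors' deposited table for Col-0, against 1.73 for the 1290 listed in both. Of the 545, 83 had an absolute log2 fold change of at least 2 in Col-0. In kai2 and max2, 697 and 786 Col-0 genes were not listed, 136 and 144 of them at that size in Col-0. Whether these genes responded less in the mutants was not tested.

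Whether the response differed between d14 and Col-0, the question behind the title, could be tested only on the 1290 genes listed in both tables. These had kept a change past the authors' threshold in d14, so a response lost there could not be found. The tests against kai2 and max2 were limited in the same way. In d14 the difference passed the threshold for 102 genes, of which 97 changed more strongly in d14, 2 less strongly and 3 in opposite directions. NADP-ME1 rose by 3.85 ± 0.35 on the log2 scale in Col-0 and by 6.05 ± 0.47 in d14, a difference of 2.205 ± 0.60 (edgeR, adjusted p = 0.035). The oxidoreductase gene AT1G64590 rose from 380.4 ± 86.6 to 966 ± 561 in Col-0 and from 255 ± 78.9 to 4227 ± 1169 in d14, a difference of 2.71 ± 0.45 (adjusted p = 0.00547). Its rise in Col-0 had an adjusted p of 0.0228, and of 0.0632, 0.0872 and 0.0936 without Col-0 zaxinone replicate 1 and mock replicates 1 and 2. SOUL-1, a heme-binding protein gene, differed between d14 and Col-0 by 2.72 ± 0.70 (adjusted p = 0.0274). In d14 zaxinone replicate 1 its normalized count was 1699.5 against 422 to 479 in the other d14 zaxinone libraries. MAM1 of glucosinolate synthesis fell further in d14, with a difference of -1.07 ± 0.27 (adjusted p = 0.0248), as did the F-box gene AT1G80470, with a difference of -1.68 ± 0.34 (adjusted p = 0.00898). The 3 genes with opposite directions were AT3G55513, AT2G05350 and AT5G50550, with differences of 2.65 ± 0.57, -3.68 ± 0.99 and -4.18 ± 0.87, and the 2 with a weaker change were AT4G08380 and AT5G06630. AT2G05350 and AT5G06630 were named after their values were seen.

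Among the 713 genes that rose in both genotypes, 79.8% had the larger fold change in d14 in the authors' deposited tables, with a median difference of 0.48 on the log2 scale. The 574 genes that fell in both had a median difference of 0.00 there. Of the lists with at least 5 members in both tables, heat shock, suberin, abscisic acid response and detoxification genes had median differences of 0.89, 0.87, 0.61 and 0.54. For low oxygen genes it was 0.82, with 9 of 10 positive and medians of -2.59 in Col-0 and -1.82 in d14, so that most of these genes fell less in d14, and for immune and glucosinolate genes it was 0.17 and -0.19. No list passed the test of the list difference in any mutant, which was added after the results were seen (fry, lowest adjusted p = 0.121). In max2 the abscisic acid response list went the other way than in d14. Its median difference from Col-0 was -0.42, with 2 of 11 members positive (fry, adjusted p = 0.278). The d14 count of 102 moved with single libraries. Without Col-0 zaxinone replicates 1, 2, 3 and 4 it was 156, 55, 51 and 33, without Col-0 mock replicates 3 and 4 it was 57 each, without d14 zaxinone replicates 1 and 4 it was 47 and 57, and without d14 mock replicates 1, 2 and 3 it was 33, 49 and 47. DESeq2 gave 200 genes.

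For kai2, 1138 genes were listed in both tables, and the fold changes of the 599 that rose in both differed from Col-0 by a median of 0.10 in the authors' deposited tables. No gene passed the edgeR test of the difference, where 98 had an unadjusted p under 0.05 and DESeq2 gave 16. The median 95% interval of a single gene's difference reached 0.70 on the log2 scale to either side. In simulated counts with 200 changed genes the test recovered 41% of differences of 1 and 81% of differences of 2. A difference of 1 would thus often be missed, and more often with fewer true differences. Without Col-0 zaxinone replicates 1 and 2 the count was 6 and 9, and without kai2 zaxinone replicate 1 or kai2 mock replicate 2 it was 2 each. It was 3 with TMM over the shared genes and 6 with all 32 libraries in a single fit.

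Against max2 the difference passed for 27 of 1049 genes, 13 of them with a weaker change in max2, 4 with a stronger one and 10 with opposite directions. NCED3 rose less in max2, with a difference of -1.90 ± 0.33 (edgeR, adjusted p = 0.00273), as did AT1G07985 at -2.32 ± 0.42, the acyltransferase gene PMAT1 at -1.91 ± 0.40 and AT1G60750 at -1.86 ± 0.49. The 4 with a stronger change in max2, named after their values were seen, were AT1G64590, AT4G12735, UGT73B3 and PGIP1. Opposite directions were listed in the authors' deposited tables for the wound-responsive family genes WIP4, AT4G33560 and AT4G10265, though with edgeR the max2 side did not pass for the first 2: in max2 WIP4 and AT4G33560 had adjusted p of 0.0592 and 0.0856. AT4G10265 changed by -2.69 ± 0.66 in Col-0 (adjusted p = 0.0227), a call lost with limma-voom (0.241) and without Col-0 zaxinone replicates 1 and 3 and mock replicates 1 and 2 (0.0789, 0.0937, 0.0941 and 0.102), and by 2.34 ± 0.48 in max2 (0.00928, and 0.0643 with TMM over the listed genes). WIP4 fell from 1344 ± 999 to 135 ± 66.9 in Col-0, a difference of 5.08 ± 0.80 (adjusted p = 0.00212), and AT4G33560 fell from 399.5 ± 367 to 25.8 ± 14.6 in Col-0 and went from 147 ± 99.2 to 709.8 ± 462 in max2. AT5G50550 went the other way, rising from 60.8 ± 50.8 to 258 ± 61.9 in Col-0 and going from 120.4 ± 71.1 to 25.7 ± 20.5 in max2 (adjusted p = 0.0742). DESeq2 gave 57 genes.

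**Figure D3:**
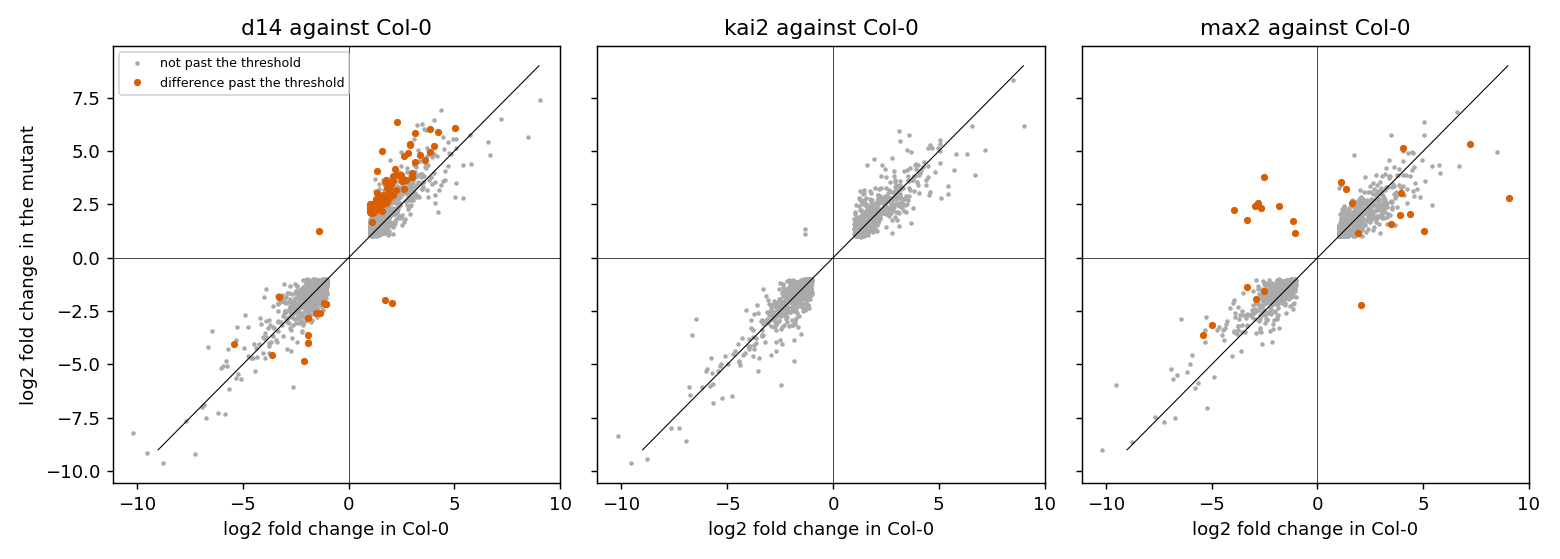
Each point is a gene listed in both tables, with its edgeR log2 fold change in Col-0 on the x axis and in the mutant on the y axis (1290, 1138 and 1049 genes). Orange points are the 102, 0 and 27 genes whose difference passed the test, the line marks equal change, and the empty band around 0 holds the genes that the authors' tables leave out.

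Mock-treated mutants were compared with mock-treated Col-0 over the same shared genes, on the log2 scale (± SE, n = 4 libraries per group). In d14 mock roots UGT73B2 differed from Col-0 by -1.13 ± 0.16, the abscisic acid response gene ABF3 by -0.85 ± 0.13 and BCH1 by -0.89 ± 0.20, all 3 genes that rose with zaxinone, while HB1 differed by 1.42 ± 0.31 and G6PD3 by 1.18 ± 0.17, genes that fell. In max2 mock roots CYP81D11 differed by -1.94 ± 0.34 and ABF3 by -1.26 ± 0.17, and NCED3 was higher, by 1.495 ± 0.27. In kai2 mock roots HRE1 differed by -0.62 ± 0.14 and the F-box gene AT1G80470 by 1.76 ± 0.21. These genes were chosen from the named ones after their values were seen. In d14, 384 genes differed, 211 higher and 173 lower, in kai2 123, 100 higher and 23 lower, and in max2 287, 204 higher and 83 lower (edgeR, library totals). Of the genes higher in d14, 189 were genes that fell with zaxinone in Col-0 and 22 were genes that rose, and of those lower in d14, 164 had risen and 9 had fallen. In kai2 82 of the higher genes had fallen with zaxinone and 18 had risen, and of the lower ones 10 had risen and 13 had fallen. In max2 171 of the higher genes had fallen and 33 had risen, and 75 of the lower ones had risen and 8 had fallen.

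The 3 mock comparisons share the Col-0 mock libraries, and their genes had been selected on the same libraries. With TMM over the shared genes the splits were 157 higher and 218 lower in d14, 85 and 51 in kai2, and 123 and 136 in max2, after shifts of the median by -0.09, -0.12 and -0.21. Without Col-0 mock replicate 4 the counts were 232, 43 and 167. The d14 count was 243 and 215 without d14 mock replicates 1 and 2. The kai2 count was 65 without Col-0 mock replicate 1 and 63 and 52 without kai2 mock replicates 2 and 3, and the max2 count was 181 and 182 without max2 mock replicates 2 and 3. Without kai2 mock replicate 1 the kai2 split was 76 higher and 35 lower.

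**Figure D4:**
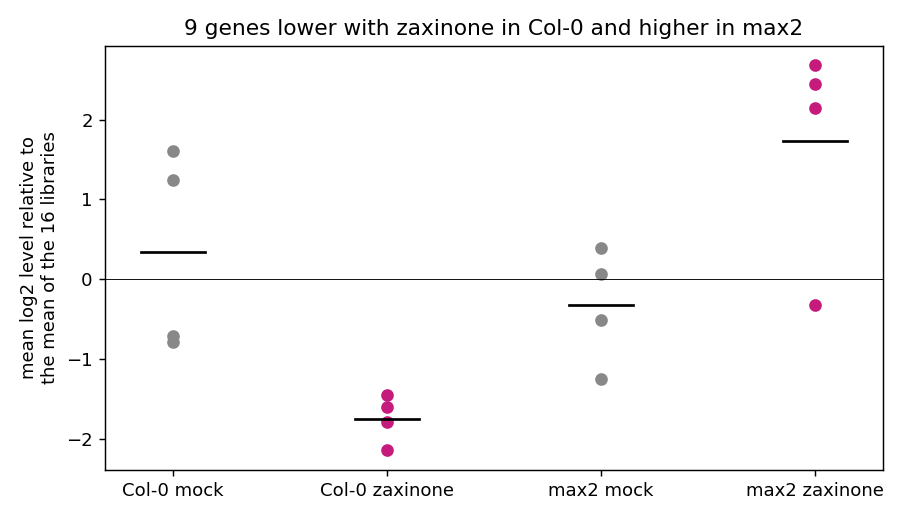
Points are single libraries and lines group means of 4, for the mean log2 level of 9 genes that the authors' deposited tables give as lower with zaxinone in Col-0 and higher in max2, relative to the mean of the 16 libraries. The genes were chosen for these directions, and the spread within groups is wide, from -0.79 to 1.61 in Col-0 mock and from -0.32 to 2.68 in max2 zaxinone libraries.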

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

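Of the tests in this part, those of scaling, of the spread within groups, of other groupings of the libraries and of the mock levels without single mock libraries were chosen only after the results were seen.

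For each named gene and group of 4 libraries, the highest or lowest library was compared with the other 3, and it stood far apart (Dixon's criterion for 4 values) in 81 of 822 groups. That is 9.85% of groups, where independent normally distributed values would give about 1 in 20. The counts were not transformed, and in groups with hardly any reads a single read can pass. Genes of a library are not independent either, so an excess over chance is not established. Values are normalized counts in the library named, against the range of the other 3 libraries of its group. The libraries with the most such values, 12 each, were d14 zaxinone replicate 1, kai2 mock replicate 1 and kai2 zaxinone replicate 1.

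ABCG40 stood at 0.995 against 9.58 to 11.1 in Col-0 mock replicate 2. HSFA6B stood at 467 against 224 to 245, ARR15 at 29.2 against 8.79 to 10.5, SWEET1 at 44.5 against 26.7 to 28.3 and HB1 at 2664 against 4518 to 4889 in Col-0 zaxinone replicate 3. F3H stood at 165 against 89.9 to 95.4 and AT5G50550 at 166 against 279 to 299.9 in Col-0 zaxinone replicate 3. AT4G19750 stood at 1055 against 2064 to 2190.2, CKX5 at 172 against 131 to 135 and AT5G50550 at 137 against 28.8 to 40.6 in Col-0 mock replicate 1. AT5G23903 stood at 7.20 against 0 to 1.16 in Col-0 zaxinone replicate 1. CYP707A1 stood at 662 against 767 to 784, LSU1 at 10.5 against 34.2 to 36.9 and AT3G55513 at 61.6 against 40.5 to 43.7 in Col-0 zaxinone replicate 4. JAZ7 stood at 225 against 105 to 118 in Col-0 mock replicate 4. RNS1 stood at 208 against 48.6 to 59.3 and ZIP10 at 0.977 against 0 in Col-0 zaxinone replicate 2. OPR1 stood at 1444 against 1144 to 1184 in Col-0 mock replicate 3. AT4G33467 stood at 893 against 142 to 269.5, SOUL-1 at 1699.5 against 422 to 479, GRP3S at 3916 against 1425 to 1720.1 and ERF5 at 2698 against 1941 to 2053 in d14 zaxinone replicate 1. LSU1 stood at 75.2 against 15.2 to 23.5, SWEET12 at 7104 against 1767 to 2632, KMD4 at 21612 against 15213 to 15700.3 and BGLU30 at 24091 against 1965 to 4724 in d14 zaxinone replicate 1. HB1 stood at 6635 against 10220.0 to 10869, HSP17.4 at 441 against 136 to 184, ZAT12 at 13544 against 7061 to 7959.8 and AT1G52342 at 5884 against 1445 to 1985 in d14 zaxinone replicate 1. AT1G51810 stood at 1.27 against 0 and AT1G07680 at 13.95 against 0 to 0.94 in d14 zaxinone replicate 4. HB40 stood at 32.7 against 14.5 to 15.4 in d14 mock replicate 2. NCED2 stood at 30.2 against 9.78 to 12.2, RD29A at 1453 against 2936 to 3209 and DREB2A at 1443 against 3279.7 to 3535 in d14 zaxinone replicate 2. NIR1 stood at 31283 against 35225 to 35809 and BGLU23 at 40314 against 43761 to 44430.1 in d14 mock replicate 4. 4CL3 stood at 20.9 against 13.6 to 14.7 and ABCG40 at 12.1 against 7.24 to 7.90 in d14 mock replicate 1. RBCS2B stood at 1.09 against 0 and ABCG40 at 540.2 against 303 to 340.3 in d14 zaxinone replicate 3. UGT73B2 stood at 288 against 127 to 152, CCD7 at 56.9 against 6.12 to 11.9, ARR5 at 1282 against 898 to 961 and PAD3 at 619.9 against 273 to 318 in kai2 mock replicate 1. ACO1 stood at 10590.1 against 2410.1 to 3398, PPC3 at 5701 against 3629 to 3833, GAPC1 at 35886 against 24195 to 24921 and HB1 at 51508 against 6829 to 10974 in kai2 mock replicate 1. PCO2 stood at 6199.7 against 695 to 1418, AOX1A at 1201 against 530.1 to 627, RBCS2B at 23.3 against 1.22 to 3.96 and LHCB1.2 at 94.3 against 2.45 to 11.9 in kai2 mock replicate 1. LEA7 stood at 879 against 222 to 299, ABI2 at 2167 against 1392 to 1459, HB7 at 7281 against 4568 to 4741 and RD26 at 3799.9 against 2363 to 2484 in kai2 zaxinone replicate 1. VSP1 stood at 2106 against 1020.3 to 1203, SARD1 at 575 against 370.4 to 388, PAP17 at 3795 against 1720.0 to 1814 and NAS1 at 636 against 847 to 880.5 in kai2 zaxinone replicate 1. DREB2A stood at 4078 against 2599.6 to 2829, AOX1A at 3326 against 2891 to 2958, PRR9 at 199 against 88.1 to 107 and F3H at 65.8 against 27.6 to 29.8 in kai2 zaxinone replicate 1. CYP81D11 stood at 191 against 97.1 to 111 and PAP17 at 1304 against 266 to 388 in kai2 mock replicate 4. AT1G51810 stood at 0.89 against 0 in kai2 zaxinone replicate 4. AT4G08380 stood at 114 against 58.8 to 60.8 and KCS2 at 2304 against 1614 to 1720.0 in kai2 zaxinone replicate 2. LHCB1.2 stood at 11.2 against 0.774 to 1.84 in kai2 zaxinone replicate 3. AT4G19760 stood at 53.5 against 24.6 to 26.6 and AT4G19750 at 186 against 54.8 to 64.5 in max2 zaxinone replicate 4. NCED2 stood at 4.98 against 15.2 to 16.1 and NIMIN1 at 61.7 against 26.6 to 31.0 in max2 zaxinone replicate 1. PPC3 stood at 5824 against 4713 to 4899, DREB2A at 469 against 532 to 537 and DRT112 at 134 against 3.27 to 21.0 in max2 mock replicate 4. AT3G03341 stood at 2.21 against 0 in max2 mock replicate 3. AT1G51810 stood at 113 against 44.3 to 51.3 in max2 mock replicate 1.

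The zaxinone effect of 20 named genes differed between a mutant and Col-0 in the edgeR test of the difference, given here as mutant minus Col-0 on the log2 scale (± SE, n = 4 libraries per group). In d14 the differences were NADP-ME1 2.205 ± 0.60, SOUL-1 2.72 ± 0.70, MAM1 -1.07 ± 0.27, AT1G64590 2.71 ± 0.45, AT3G55513 2.65 ± 0.57, AT1G52342 2.42 ± 0.48, AT2G41580 -2.76 ± 0.68, AT1G80470 -1.68 ± 0.34, AT2G02690 -1.28 ± 0.34 and AT4G36850 -1.10 ± 0.27. In max2 they were AT1G60750 -1.86 ± 0.49, NCED3 -1.90 ± 0.33, WIP4 5.08 ± 0.80, AT4G33560 6.21 ± 1.09, AT1G12805 5.34 ± 0.90, AT4G10265 5.04 ± 0.92, AT4G28811 4.22 ± 0.90, AT5G50550 -4.29 ± 0.84, AT1G07985 -2.32 ± 0.42 and PMAT1 -1.91 ± 0.40.

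Genes that rose with zaxinone in both Col-0 and d14 had the larger fold change in d14, by a median of 0.44 on the log2 scale over 713 genes (from group means of log2 scaled counts). In mock roots the same genes had a median difference of -0.24 between d14 and Col-0 (log2, library totals). A lower mock level in d14 may thus hold part of the larger fold change, and its share was not tested. A single factor from the authors' scaling would move falling genes alike. Over the full data and with each of the 16 libraries left out, the median difference of the 574 falling genes was at most 0.0733, which argues against scaling alone. A single library is argued against as well, since the lowest median of the rising genes was 0.341, found without d14 zaxinone replicate 1. A response that differs between d14 and Col-0 may account for the pattern, as a hypothesis found and tested on the same libraries. Differences in growth or handling between the genotypes were not tested and stay open.

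Genes that fell with zaxinone lay higher in mutant than in Col-0 mock roots, relative to genes that rose, by 0.61 in d14, 0.45 in max2 and 0.13 in kai2 (difference of medians, log2). Scaling between the tables would move both sets alike, and for d14 and max2 the smallest difference with a mock library left out, 0.407, argues against it. For kai2 it was 0.0729, so that scaling cannot be told apart from a difference between plants, because the difference is close to 0. With 1 mock library left out, at least 0.540 of the full difference was left in each mutant. This argues against a single mock library for d14 and max2, where the difference stayed at 0.550 and 0.407 or more. In kai2 it went from 0.13 to 0.0729 without kai2 mock replicate 2, so that much of it rested on that library. The medians were 0.37 for falling and -0.24 for rising genes in d14, 0.47 and 0.0128 in max2, and 0.21 and 0.0705 in kai2. The rising medians of kai2 and max2 moved with single libraries. In kai2 it was -0.0219 and 0.154 without kai2 mock replicates 1 and 2, and in max2 -0.0317 without max2 mock replicate 3. Selection of the genes on the Col-0 mock libraries would by itself push falling genes down and rising genes up in the mutants, the reverse of the difference seen. Selection on the mutants' own mock libraries would push the other way, was not tested, and stays open beside a difference between the genotypes.

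The 9 genes lower with zaxinone in Col-0 and higher in max2 include the wound-responsive family genes WIP4, AT4G33560 and AT4G10265. All 9 passed the test of the difference without each of the 16 libraries, which argues against a single library for the difference alone. They had been selected on that test with all libraries. For the opposite directions a single library stays open. The call of AT4G10265 in Col-0 was lost in 5 other settings, among them single libraries left out, and WIP4 and AT4G33560 did not pass with edgeR in max2. A state of these genes that differed between plants within groups is a candidate explanation: their median SD within groups was 1.09 on the log2 scale, above the 95th percentile of 0.528 over 10000 random sets of shared genes matched on level. Col-0 mock replicates 1 and 2 had mean levels of 1.61 and 1.24 and replicates 3 and 4 of -0.79 and -0.71, while max2 zaxinone replicate 2 stood at -0.32 against 2.15 to 2.68 in the others. A difference between max2 and Col-0 stays open and was not tested apart from this spread.

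Other groupings of the same libraries were counted for each test. For the differences between genotypes 100 assignments of the genotype labels within treatments were drawn, the real one included. In d14 3 of 100 called as many genes as the real 102, the highest other calling 517, several times the real count, which points to a structure of the samples: exchanged labels turn differences between mock levels of the genotypes into differences of effect. In max2 3 of 100 called as many as the real 27, the highest other also 27. In kai2 all 100 called at least the real 0 genes, as any assignment must, and the highest other called 12. For the mock comparisons 1 of 35 splits, the real one, called as many genes in each mutant: the real counts were 384, 123 and 287 in d14, kai2 and max2, and the highest others 1, 0 and 4. For zaxinone against mock 1 of 35 splits reached the real 1570, 2100, 1577 and 1261 genes in Col-0, d14, kai2 and max2, with 0, 0, 0 and 3 as the highest others. All of these tests ran on genes selected for a difference between the real groups of zaxinone and mock libraries, which disfavours mixed groups in advance, so none of these counts decides whether chance can be excluded.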

How the results depend on the processing

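The tests with an absolute log2 fold change of at least 2, with library totals, with TMM scaling or a library left out in the mock comparisons, and with the tests implied as background were chosen only after the results were seen. At an absolute log2 fold change of at least 2 the authors' calls came to 560, 847, 571 and 456 genes in Col-0, d14, kai2 and max2, and to 238 shared by all 4, as the stricter threshold leaves fewer genes. With all 32 libraries in 1 fit the counts were 805, 812, 802 and 787, since only the 827 genes in all 4 tables entered. TMM over the listed genes gave 1434 in d14. Leaving out each library gave 1371 to 1475 genes in Col-0, 1926 to 2039 in d14, 1411 to 1544 in kai2 and 1095 to 1194 in max2, all within 1.5 times the authors' counts.

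For the difference of the zaxinone effect, DESeq2 gave 200 genes in d14, 16 in kai2 and 57 in max2, in place of 102, 0 and 27. In kai2 TMM over the shared genes gave 3 and the fit of all 32 libraries 6. Leaving out each library gave 33 to 156 in d14, 0 to 9 in kai2 and 19 to 31 in max2. In the mock comparisons it gave 215 to 404 in d14, 43 to 113 in kai2 and 167 to 309 in max2. With the background of listed genes 19 list calls were made in place of 42. Where no construction is named, the cause was not tested.

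The replicate number as a block gave 1560, 2029, 1489 and 1135 genes in the 4 zaxinone comparisons and 79, 0 and 23 in the differences. Replicate numbers did not pair the samples: mock and zaxinone libraries of the same number had correlations across genes of -0.19 to 0.21, and 4 of 16 libraries matched best with their own number. Of 411 named gene and genotype pairs, the block kept 394 on their side of the threshold, with 11 weaker, 6 stronger and 0 reversed. Leaving out a library kept 3104 of 3288 values, with 152 weaker, 32 stronger and 0 reversed, and the other settings kept 1939 of 2033, with 57 weaker, 37 stronger and 0 reversed. A camera test and settings for normalized values (pseudocount, quantile scaling) were not run, as the tables hold counts of selected genes. With 4 libraries per group the median 95% interval of a difference between genotypes reached 0.69 in d14, 0.70 in kai2 and 0.69 in max2 to either side on the log2 scale.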

Other observations

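No tests in this part were chosen after the results were seen. Sugar, flavonoid and glycolysis genes had single members past the authors' threshold beside lists that mostly did not pass. The flavonoid gene F3H rose in all 4 genotypes, by 1.81 ± 0.37, 2.74 ± 0.38, 2.60 ± 0.44 and 2.61 ± 0.497 in Col-0, d14, kai2 and max2 (log2 ± SE, n = 4 libraries per group). The cytochrome P450 gene CYP71A12 rose by 1.59 ± 0.22, 2.92 ± 0.20, 1.38 ± 0.28 and 1.63 ± 0.26, with an adjusted p of 0.0787 in kai2 with TMM over the listed genes. PPC3, a phosphoenolpyruvate carboxylase gene, rose by 1.09 ± 0.25 in Col-0, 1.197 ± 0.14 in d14, 1.85 ± 0.19 in kai2 and 1.28 ± 0.15 in max2. Its adjusted p in Col-0 was 0.0136 with edgeR, and 0.0536 and 0.0521 without Col-0 zaxinone replicate 1 and mock replicate 4, and in d14 the change was 0.30 (adjusted p = 1) with TMM over the listed genes. The hexose transporter gene STP13 rose by 1.71 ± 0.20 in d14 and 1.44 ± 0.20 in max2, and STP4, of the same family, changed by -1.13 ± 0.15 in kai2. The sucrose transporter family gene SWEET13 was listed as higher in all 4 genotypes, with changes of 1.72 ± 0.52, 2.67 ± 0.28, 1.77 ± 0.55 and 1.70 ± 0.40 in Col-0, d14, kai2 and max2 and edgeR adjusted p of 0.0841, 3.4e-05, 0.112 and 0.0234. In max2 the adjusted p was 0.0695, 0.0870, 0.0531 and 0.0794 without max2 zaxinone replicates 2 and 3 and mock replicates 2 and 3, 0.104 with the replicate number as a block and 0.181 with TMM over the listed genes. The ethylene response factor gene ERF1 changed by -1.39 ± 0.24 and the jasmonate repressor gene JAZ9 by -1.27 ± 0.19 in d14.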
